A study of Cucumis melo with 6 samples.

How the data were processed

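Gene expression was measured by strand-specific poly(A) RNA sequencing in leaves of 2 genotypes of melon (Cucumis melo, a Charentais-type cantaloupe line). There were 3 libraries from the monoecious wild type (WT) and 3 from the double mutant lhp1ab, which carries chemically induced mutations in CmLHP1A and CmLHP1B. Per the labels' protocols, plants were grown in a glasshouse with 16 h of light at 27 °C and 8 h of darkness at 21 °C, at a relative humidity of 60%. RNA was taken from 1 g of fresh leaf, and each library was made from 2 µg of total RNA with a directional kit. The series calls the replicates biological. Whether each came from a separate plant or from a pool is not given in the sources used here, so p-values measure the spread between these samples.

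The deposited files hold raw read counts per gene, 1 file per library, which the authors made with featureCounts 1.6.4, per the file headers. The headers record counting over exons grouped by gene, reverse-stranded (setting 2), with a minimum mapping quality of 30, from 1 alignment per library and without pairing of reads. They also record that reads overlapping several genes were counted for each of these genes, and that multi-mapping reads were allowed. The annotation is named in the headers as a liftover onto release 4.0 of the melon genome, and all coordinates below are on that release. Trimmomatic 0.38, STAR, R 3.5.1 and DESeq2 are listed in the submitters' processing notes, and the STAR and DESeq2 versions are not given in the sources used here. The reverse-stranded setting fits a directional kit of this type, so genes on opposite strands were counted apart. Genes overlapping on the same strand share reads under this setting. Such overlap of gene spans concerned 2112 of the 28299 genes (7.46%). Whether multi-mapping reads reached the counts depends on the mapping qualities that the aligner gave them, so counts of near-identical gene copies are uncertain.

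The gene identifiers are those of an automated annotation, and the files pair none of them with a gene name or product. None of the 28299 identifiers occurs in the reference gene table used here (28628 genes of another melon assembly), and no coordinates were carried between assemblies. The planned tests of gene lists matched by product description (Polycomb, floral, hormone, photosynthesis and cell type marker lists) were therefore not run. CmLHP1A and CmLHP1B could not be looked up in these tables, so the targeted genes were not checked in the libraries. Genes are described by their position, exon number, exon length and expression level. The files hold exons only, so coding parts and untranslated regions are not told apart.

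Totals per library ranged from 20551374 to 22366054 counts in WT and from 15335390 to 17647188 in lhp1ab. A count of 0 allows up to 3 counts, which is 0.134 to 0.146 CPM in WT and 0.170 to 0.196 CPM in lhp1ab. CPM here are counts scaled to a common library total. Such floors and all count intervals cover counting error only, since the reads carry no molecular identifiers. Replicates of a genotype were compared by a chi-square test of their counts over genes. The statistic per degree of freedom was 2.17 to 6.78 in WT and 3.53 to 11.8 in lhp1ab, so no pair agreed within the sampling noise of independent reads. Several reads from the same molecule would raise this statistic too, so it cannot tell whether the replicates are biological. Each library was counted as 1 replicate because the series calls them biological.

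The main test was edgeR 4.0.16's quasi-likelihood F-test (two-sided) in R 4.3.3 on the counts as deposited, with TMM normalization, edgeR's default filter on low counts by genotype and no covariates. Calls were made at a Benjamini-Hochberg adjusted p of 0.05. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of the F statistic. A test against a 1.5-fold change (glmTreat) was run on the same fit. On simulated counts for the 17988 tested genes, with 200 genes changed, the main test recovered 24% of the genes changed 1.25-fold, 74% of those changed 1.5-fold, 90% of those changed 2-fold and 98% of those changed 4-fold. In that simulation 8.92% of the calls were unchanged genes. The data held far more changed genes, with 13579 called, so the adjusted threshold falls at a larger p there. These rates therefore do not carry over to the real test.

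Detection was compared after thinning each library once at random to 15335390 counts. Genes near a limit of the rule below could pass or fail it in another draw, and no other draw was made. A gene was called switched on where every lhp1ab library held at least 10 thinned counts and every WT library at most 1, and switched off in the opposite case. Calls were compared between chromosomes by Fisher's exact test, and between quartiles of mean expression over all 6 libraries in the same way. The share of called genes whose next tested gene along the chromosome was called in the same direction was set against 10000 shufflings of the calls within chromosomes. Values per library were compared by exact permutation tests, which cannot go below p = 0.1 with 3 libraries against 3. Genes are not independent replicates, so tests across genes describe these libraries.

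Before the data were examined, a rule was set for the genes named in the text. It took called genes whose genotypes did not overlap and that had a mean of at least 5 CPM in the higher genotype, and ranked them by fold change. With no gene names at hand it allowed 2 genes in each direction. Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE and upper quartile normalization, library totals alone, 2 other filters, leaving out the 20 most abundant genes, the replicate number as a block, and leaving out each library in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps. Self-tests on planted calls were run on the neighbour and chromosome tests.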

Results

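Leaf transcriptomes were compared between monoecious wild-type (WT) melon plants and the double mutant lhp1ab, with 3 libraries per genotype. Monoecious plants bear separate male and female flowers on one plant. LHP1 proteins are plant chromodomain proteins that bind histone H3 trimethylated at lysine 27, the mark set by Polycomb proteins at silent genes. The series asks, by its title, what part the CmLHP1 proteins play in melon development and in keeping the plants monoecious. Per the labels, the mutant carries chemically induced mutations in CmLHP1A and CmLHP1B. Counts were available for 28299 genes, of which 1 was an unplaced gene model without reads and the others lay on 12 chromosomes. Mean totals were 21220799 ± 996532 counts in WT and 16539314 ± 1158888 in lhp1ab (SD, n = 3). Replicates of a genotype resembled each other far more than the genotypes did. Pearson's r of log2 CPM across genes lay between 0.995 and 0.996 within WT, between 0.989 and 0.992 within lhp1ab, and between 0.834 and 0.842 across genotypes. The first principal component separated the genotypes and held 94.2% of the variance. The spread between replicates beyond counting noise, as edgeR's biological coefficient of variation, was 5.13% in WT and 9.10% in lhp1ab.

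Leaf expression of the mutant differed from WT in most of the expressed genes. Of 17988 genes tested, 6646 (36.9%) were higher in lhp1ab and 6933 (38.5%) were lower, and 4409 were not called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p threshold 0.05). The median change of the called genes was 0.83 on the log2 scale, against a median SE of 0.094 over all tested genes. Both genotypes separated without overlap, all 3 libraries of one above all 3 of the other, in 77.7% of tested genes, where chance gives 10%. When a change had to exceed 1.5-fold, 7222 genes passed, 3752 of them higher and 3470 lower in lhp1ab. Which direction held more calls depended on the setting. Higher genes outnumbered lower ones with RLE normalization (6874 and 6691), without the 20 most abundant genes (6885 and 6677), with DESeq2 (6716 and 6393) and without lhp1ab replicate 1 (6984 and 6877). Over 1.5-fold, library totals alone turned the order to 3552 higher and 3714 lower.

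Large changes went upward more often than downward. At least 2-fold changes were called upward in 2997 genes and downward in 2597. At least 4-fold changes were called upward in 1235 genes and downward in 913, and at least 16-fold changes in 335 and 147. Many of the 16-fold changes were measured against a genotype with almost no reads, for which the fitted fold depends on the small count that edgeR adds. Among genes with a mean above 3 counts per library in the lower genotype, 165 were at least 16-fold higher and 109 at least 16-fold lower in lhp1ab. At 4-fold, this limit left 1011 higher and 817 lower. It was applied in the main setting only, and to raw counts. The limit was therefore looser for higher genes, as 3 counts are 0.134 to 0.146 CPM in WT and 0.170 to 0.196 CPM in lhp1ab. Without this limit, the upward excess at each of the 3 fold thresholds was present in all 18 settings of test, scaling, filter and left-out library. Its size at 2-fold was small, with a ratio of higher to lower genes between 1.02 and 1.27, and at 16-fold the ratio lay between 2.14 and 2.69. Every setting left the median log2 fold change near 0, between -0.070 with library totals alone and 0.022 with DESeq2. A shift of all genes in one direction would not be seen, so the balance of higher and lower genes rests on this scaling.

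**Figure D1:**
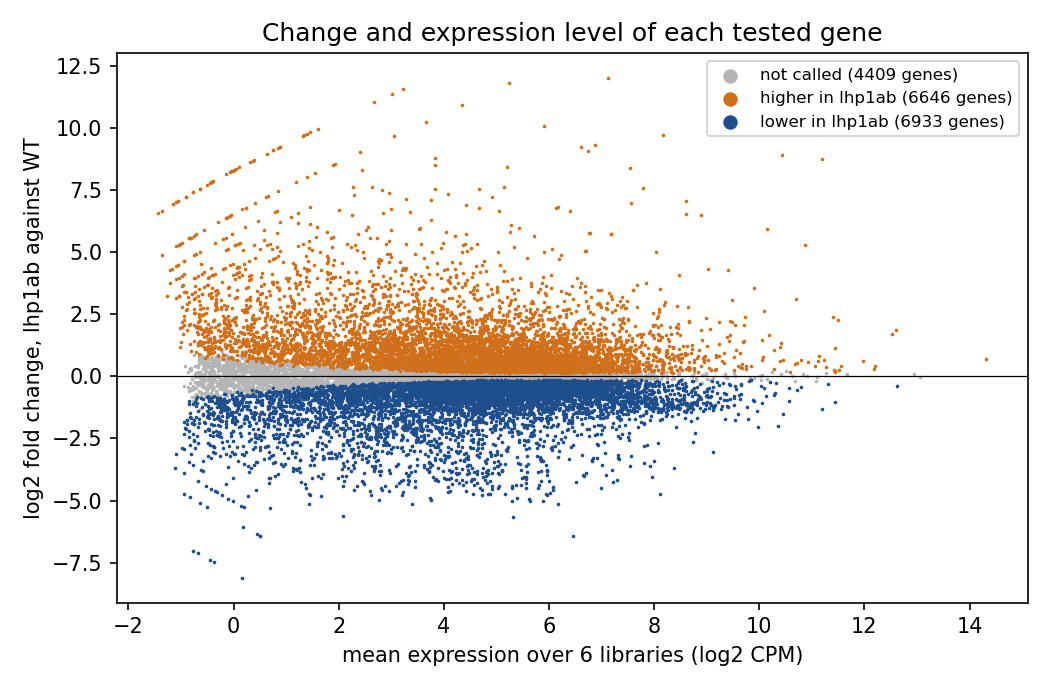
Log2 fold change of lhp1ab against WT (vertical axis) against mean expression in log2 CPM over 6 libraries (horizontal axis) for each tested gene, with 6646 called genes higher (orange), 6933 lower (blue) and 4409 not called (grey). The upper edge of the cloud reaches further from 0 than the lower edge, as the counts of 335 genes at least 16-fold higher and 147 at least 16-fold lower show.

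Among called genes with a mean of at least 5 CPM in the higher genotype, the 2 largest rises started from almost no reads in WT. The gene model maker-Chr2-exonerate_est2genome-gene-161.2, with 5 exons on chromosome 2 from 16104482 to 16108873 on the plus strand, had 0, 3 and 1 reads in the WT libraries and 280 ± 4.96 CPM in lhp1ab (SD, n = 3). Summed over libraries and scaled by their totals, the ratio was 4374, with an exact 95% counting interval of 1708 to 16054. The fitted change was 4096-fold (SE 0.18 on the log2 scale, edgeR adjusted p = 1.73e-11). The single-exon model maker-Chr11-exonerate_est2genome-gene-278.6, on chromosome 11 from 27842715 to 27843289 on the plus strand, had 1 read in 1 WT library and none in the others, against 78.0 ± 12.3 CPM in lhp1ab (SD, n = 3). Its ratio of 4873 rests on that 1 read, with an exact 95% counting interval of 874 to 192524 (edgeR log2 fold change 11.79, SE 0.29, adjusted p = 1.22e-10).

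By the same rule, the 2 largest falls left a low remaining expression. The 4-exon model maker-Chr2-exonerate_est2genome-gene-38.6, on chromosome 2 from 3785719 to 3789716 on the minus strand, went from 170 ± 15.4 CPM in WT to 1.93 ± 0.48 CPM in lhp1ab (SD, n = 3). It fell by 6.44 on the log2 scale (SE 0.14, edgeR adjusted p = 5.03e-11), which is 87.0-fold. The single-exon model maker-Chr3-exonerate_est2genome-gene-274.18, on chromosome 3 from 27478925 to 27480307 on the minus strand, went from 75.4 ± 4.56 CPM in WT (SD, n = 3) to 26, 26 and 21 reads in the lhp1ab libraries. It fell by 5.65 on the log2 scale (SE 0.10, edgeR adjusted p = 2.78e-11), which is 50.1-fold. None of the 4 gene models overlaps another on its own strand, and the first one overlaps a gene on the opposite strand. All 4 kept their direction and an adjusted p under the threshold in each alternative run. The fitted sizes of the 2 rises rest on a few WT reads: the log2 fold change of the first was 13.20 without WT replicate 2, and that of the chromosome 11 gene was 13.49 without WT replicate 1, 13.22 with thinned libraries and 11.18 with limma-voom.

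**Figure D2:**
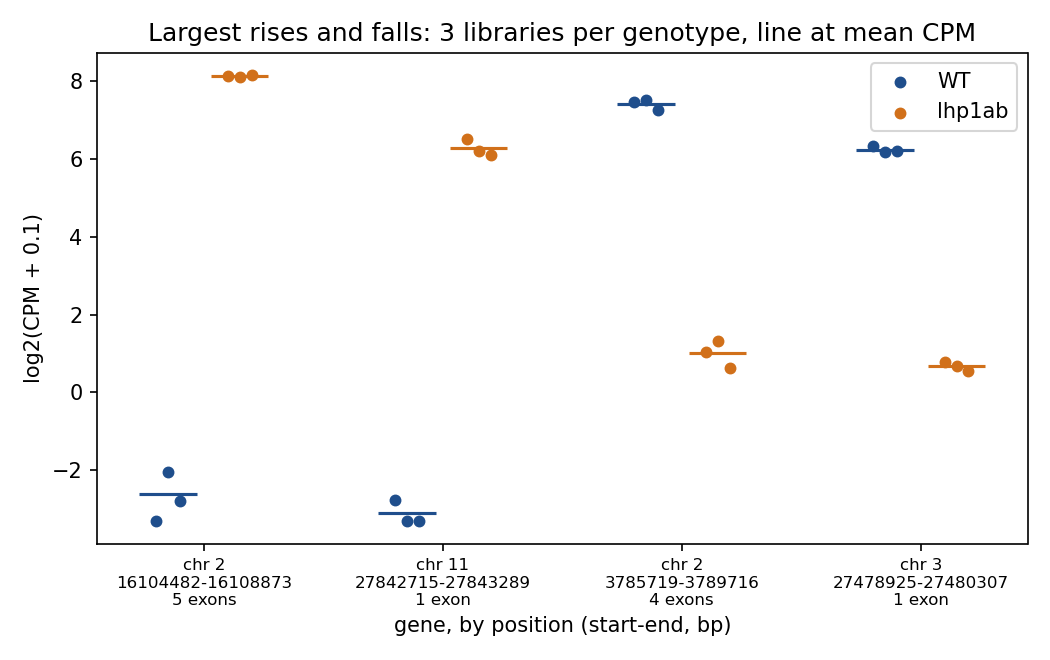
Expression as log2(CPM + 0.1) (vertical axis) in each library of WT (blue) and lhp1ab (orange) for the 2 genes with the largest rise and the 2 with the largest fall among called genes of at least 5 CPM in the higher genotype, labelled on the horizontal axis by chromosome, position and exon number; short lines mark the mean CPM of 3 libraries. In each gene the genotypes lie far apart, for instance 280 CPM in lhp1ab against 0 to 3 reads per WT library on chromosome 2.

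More genes were switched on in the mutant than were switched off. With libraries thinned to equal totals in a single random draw, 103 genes had at least 10 counts in each lhp1ab library and at most 1 in each WT library. The opposite was seen in 17 genes. The switched-on genes made up 1.21% of the 8524 genes that were silent in WT by this rule, and the switched-off genes 0.207% of the 8230 that were silent in lhp1ab. The switched-on genes had a median of 32.7 thinned counts per lhp1ab library and the switched-off genes a median of 22.7 per WT library, and the levels of the smaller set lay within those of the larger one. At least 100 counts in every expressing library were reached by 14 of the 103 and 0 of the 17 genes, and the difference in level was not tested. The number of genes with at least 10 thinned counts was 17421 ± 89.6 in lhp1ab and 17223 ± 24.0 in WT (SD, n = 3), a difference of 198 genes with all 3 mutant libraries above all 3 WT libraries. An exact two-sided permutation test gave p = 0.1, the smallest it can give with n = 3 per genotype. Before thinning, with the deeper WT libraries, the difference was -89.3 genes (exact p = 0.5). At 1 count or more it was 254.7 genes after thinning (exact p = 0.1) and 37 genes before (exact p = 0.8). The same rule without thinning gave 89 genes switched on and 23 switched off, at least 20 counts against 0 left 29 on and 1 off, and without lhp1ab replicate 1 there were 27 genes switched off and 110 switched on.

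**Figure D3:**
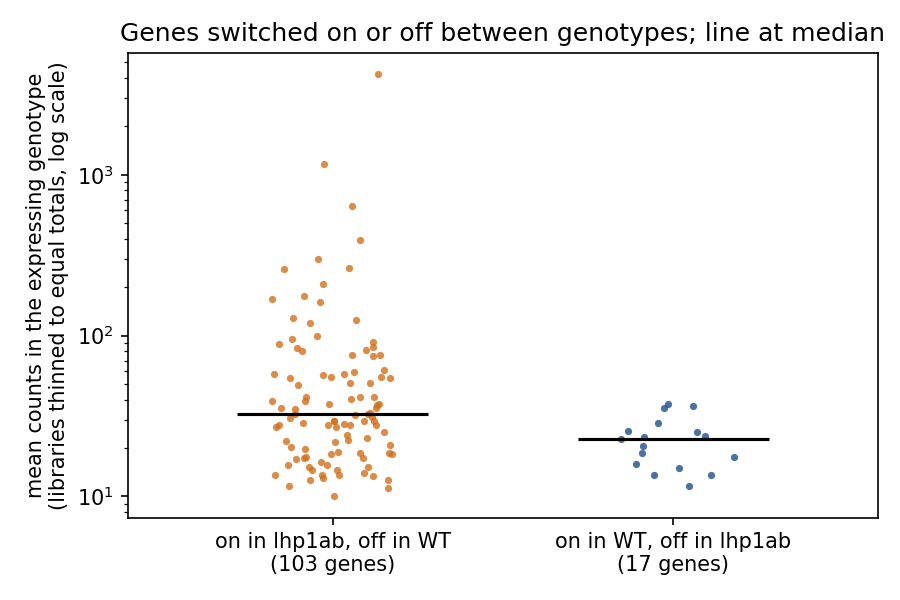
Mean thinned counts per library (vertical axis, log scale) in the expressing genotype for each of 103 genes switched on in lhp1ab (orange) and 17 genes switched off (blue), the 2 sets on the horizontal axis; black lines mark the medians of 32.7 and 22.7. The switched-off genes all lie below 100, and the switched-on genes extend above 1000.

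Upward calls made up a larger share of the calls among weakly than among strongly expressed genes. In the lowest quartile of mean expression, 1553 genes were higher and 1354 lower, so that 53.4% of calls were higher. In the highest quartile 1683 genes were higher and 2031 lower, or 45.3% higher. The odds of a call being upward were 1.38 times as large in the lowest as in the highest quartile (Fisher's exact test, two-sided, p = 6.06e-11). This ratio lay between 1.16 and 1.23 with a WT library left out, reached up to 1.89 with an lhp1ab library left out and was 1.96 without the low-count filter. The quartiles are of the mean over all 6 libraries, so a gene's change takes part in setting its quartile. The most abundant genes took a larger share of the counts in lhp1ab. The 10 most abundant genes of each library took 6.18% ± 0.123 of counts in WT and 8.44% ± 0.589 in lhp1ab, and the 100 most abundant took 19.4% ± 0.191 and 23.9% ± 1.35 (SD, n = 3; exact permutation p = 0.1 for both, the smallest possible). The difference was 4.56 percentage points at the top 100 genes, 3.78 there without lhp1ab replicate 1, and 2.97 at the top 500. The most abundant gene was the same one in all 6 libraries and took 1.59% ± 0.0368 of WT counts and 2.47% ± 0.203 of lhp1ab counts (SD, n = 3). Of the 10 genes common to the top 10 of every lhp1ab library, 6 were also in the top 10 of every WT library.

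Changed genes were spread over the whole genome. Between 73.1% (chromosome 9) and 77.2% (chromosome 3) of the tested genes of a chromosome were called. Of 24 tests for an excess or deficit of higher or lower genes on a chromosome, none passed an adjusted p of 0.05 (Fisher's exact test, two-sided), and 2 passed an unadjusted p of 0.05. Both lay on chromosome 8, where 34.7% of tested genes were higher against 37.2% elsewhere, and 40.9% were lower against 38.3% elsewhere (adjusted p = 0.54 for both).

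Neighbouring genes changed in the same direction more often than shuffled calls. Of 13570 called genes with a next tested gene on their chromosome, 43.0% had that neighbour called in the same direction, against 37.8% on average and 39.2% at most in 10000 shufflings (one-sided permutation p = 1e-04, the smallest they can give). For changes over 1.5-fold the share was 27.2% against 20.1% in shufflings (permutation p = 1e-04, again the smallest). Without genes that overlap another gene on either strand the share was 42.3% against 38.8% for all called genes and 25.9% against 21.0% for those over 1.5-fold. The longest runs of consecutive tested genes over 1.5-fold higher held 9 genes, and there were 3 of them. One spanned chromosome 3 from 27856535 to 27925597 (69.1 kb), with 7 single-exon genes among the 9, 5 genes on the plus and 4 on the minus strand, 2 that overlap a gene on their own strand, and a median log2 fold change of 2.24. The others lay on chromosome 1 from 17058700 to 17784936, with 8 of 9 genes on the minus strand and a median of 2.13, and on chromosome 12 from 16392883 to 16667504, with all 9 genes on the minus strand and a median of 2.29. The spans on chromosomes 3, 1 and 12 held 14, 43 and 21 annotated genes, since genes removed by the low-count filter are skipped in a run. A run of 9 or more higher genes occurred in 10 of 1000 shufflings. The longest runs of lower genes held 6 genes, on chromosome 1 from 31519388 to 31745584 and on chromosome 8 from 30572730 to 30617102, and 522 of 1000 shufflings had a run as long. These regions were picked by run length after their values were seen.

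**Figure D4:**
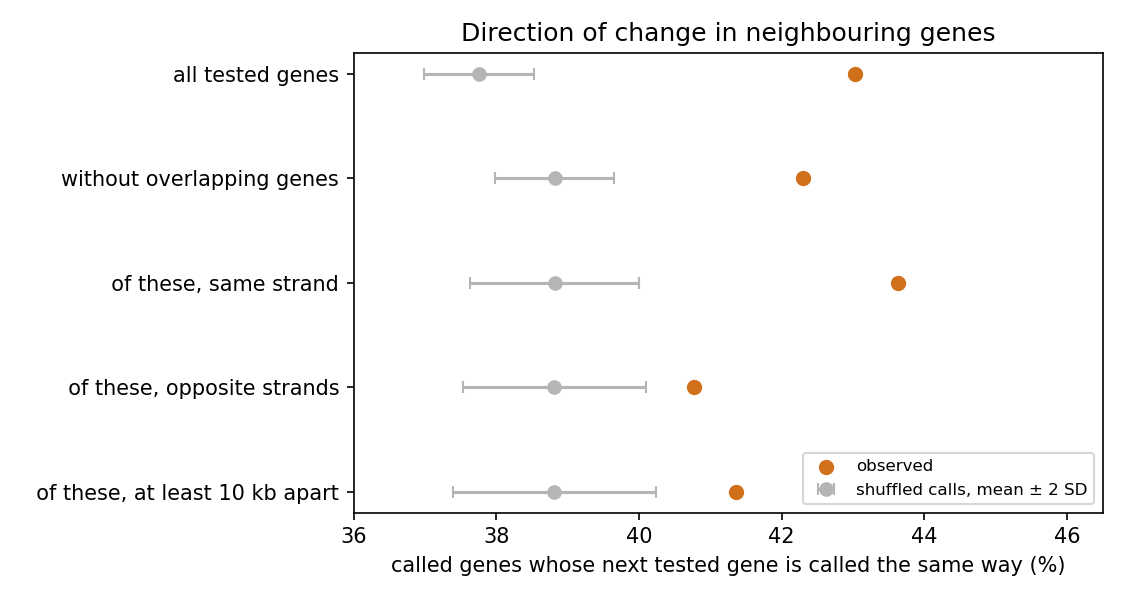
Percent of called genes whose next tested gene was called in the same direction (horizontal axis) for all tested genes, without overlapping genes, and for subsets of the latter by strand and distance (vertical axis); orange points are observed values and grey points with bars the mean ± 2 SD of shuffled calls. Each observed value lies to the right of its bar of mean ± 2 SD, from 40.8% for opposite strands to 43.6% for the same strand.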

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

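Chosen after the data were seen were thinning for the tests of changed genes, leaving out genes with same-strand overlap, leaving out libraries outside the tests of changed and named genes, RLE, library totals and the replicate block for the expression classes, and the block for chromosomes and neighbours. Over the 10 other tests, scalings, filters and gene sets without a replicate block, 13109 to 14148 genes were called, and 12736 to 13861 when each library was left out in turn, none in the opposite direction to the main test. Only a replicate number links samples of the 2 genotypes in the labels. Deviations of same-numbered libraries correlated at 0.0035, 0.093 and -0.12, and not every library correlated best with its own number. Differently numbered libraries correlated between -0.22 (WT 2 with lhp1ab 1) and 0.20 (WT 3 with lhp1ab 1), so a pairing under other numbers is not excluded. With the replicate block 13297 genes were called. The number of genes over 1.5-fold lay between 6917 and 7591, or between 6943 and 7371 with a library left out. Of the values recomputed under alternatives, 336 kept their direction and side of the threshold, or their size within 1.5 times for counts, and 5 counts of switched genes moved further. The 336 include detected genes and library composition, whose exact permutation test cannot go below p = 0.1, so only their direction could change. Many of the others are overlapping counts from the same fits. Requiring at least 20 counts against 0 gave 29 genes on and 1 off, and at least 5 against at most 1 gave 158 on and 36 off, as fewer or more genes can meet each limit. With each library left out, 110 to 126 genes were on and 19 to 27 off, and the 27 came without lhp1ab replicate 1. The difference in genes with at least 10 counts reversed to -89.3 without thinning, and that at 1 count or more fell from 254.7 to 37, where WT totals were 1.28 times as large. The gene list tests were not run, for want of gene names, and neither was leaving out unplaced genes, since none was tested. Depth limits the genes near the floor of 3 counts, where fitted folds carry no bound.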

Other observations

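The tests of gene structure, of switched-on neighbours and chromosomes, of called genes in thinned libraries and of neighbours on opposite strands were chosen after the results were seen. The other normalizations, leaving out abundant genes, the chromosome shares, and the neighbours without overlapping genes were planned before, but these and the splits were taken up as tests of explanations after the results were seen. Outcomes of the tests of overlap for switched genes, itself added after the data were seen, and of shared expression level were written down before they were run. Switching on in lhp1ab occurred in 30 of 3967 single-exon genes silent in WT (0.756%, exact 95% interval 0.511 to 1.08%) and in 73 of 4557 with several exons (1.26 to 2.01%), with an odds ratio of 0.47 (Fisher's exact test, two-sided, p = 0.000321). This difference did not keep one direction within 3 equal classes of exon length. The shares were 0.552% for single-exon genes and 0.611% for the others in the shortest class, 3.32% and 2.49% in the middle class, and 0 of 46 genes (up to 7.71%) and 5.12% of 332 in the longest class. Over all gene structures the share was 0.577% in the shortest, 2.62% in the middle and 4.50% in the longest class, and longer genes gather more reads at a given level. Of the 103 switched-on genes, 9.71% were followed along the chromosome by another switched-on gene among those silent in WT, against 1.18% on average and 7.84% at most in 10000 shufflings (permutation p = 1e-04, the smallest they can give). Without overlapping genes the share was 8.42%, against 1.40% on average and 7.37% at most. The shufflings treated all genes silent in WT alike, although 7739 were silent in both genotypes and switching on rose with exon length. No chromosome of the 12 passed a test for an excess or deficit of switched-on genes (Fisher's exact test, lowest adjusted p = 0.70).

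Of 2783 single-exon genes tested, 1072 were higher and 921 lower in lhp1ab, and at least 4-fold changes were upward in 333 and downward in 187. Of 15205 tested genes with several exons, 5574 were higher and 6012 lower, with 902 upward and 726 downward at 4-fold. The medians of log2 fold change were 0.08 and -0.03, and no test of this difference was run.

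Changed genes numbered 13579 of 17988. Thinning all libraries to the smallest total left 13238 calls, and the lowest count over 3 other normalizations and without the 20 most abundant genes was 13546, which argues against depth and against a scaling moved by a few genes. Changes only in genes on a segment linked to the induced mutations are argued against by the chromosome with the fewest calls, where 73.1% of tested genes were called, which leaves open effects of such a segment on genes elsewhere. Of the 10 splits of the 6 libraries, 1, the real one, gave as many (13579, and 7222 over 1.5-fold). The highest other had 0 for both in edgeR, with up to 134 genes at an unadjusted p under 0.05. Every other split puts libraries of both genotypes in each group, so the genotype difference widens the spread within groups and lowers the calls. The 10 splits are also too few for a share under 0.05, so they decide nothing. Loss of the LHP1 proteins, other induced mutations in the line and differences in leaf stage or growth remain open, since each would follow the genotype. No batch is named in the labels, and an effect of handling or sequencing each genotype apart would follow the genotype as well.

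The ratio of genes switched on to genes switched off was 6.06 at equal totals and 3.87 without thinning, and as equal totals are part of the rule this does not test depth. It was 5.76 without genes that overlap another on the same strand, which argues against shared reads. Of the 10 splits, 1, the real one, had as many as 120 genes on in one group and off in the other, and the highest other had 0. Every other split mixes the genotypes, so a gene that follows the genotype cannot meet the rule there. With too few splits for a share under 0.05 as well, they decide nothing. The genotype itself stays open, untested, since no measurement of chromatin was used here. A different mix of tissues or cell types in the mutant leaves stays open, since no marker gene could be named.

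The tendency of neighbours to change together remained at 42.3% without overlapping genes, against 38.8% in shufflings, so reads shared by overlapping genes could not produce all of it. Neighbours on opposite strands, which were counted apart, reached 40.8% against 38.8% on average and 41.2% at most in shufflings (permutation p = 0.0009). Where reads kept their strand, which was not measured, this argues against reads running on from one gene into the next as the whole source. The larger share on the same strand, 43.6%, and the runs with 8 and 9 of 9 genes on the minus strand leave room for a part from such reads or from near-identical tandem copies, which was not tested. Shuffling within chromosome and expression decile left an excess of 3.46 percentage points (permutation p = 1e-04, the smallest they can give), so a shared expression level does not account for it. No biological explanation was tested.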
